A study of Mus musculus with 12 samples.

How the data were processed

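RNA from 12 cultures of 4T1 cells was sequenced after removal of ribosomal RNA with RNase H, reverse transcription with random hexamers and 12 cycles of amplification, as paired reads of 150 bases on an Illumina NovaSeq instrument, per the labels' protocols. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.1a and featureCounts 1.4.6-p5 of the Subread package. The genome build, annotation, strand setting and rule for reads that map to several places are not given in the sources used here. The deposited values are raw counts of reads per gene symbol, with 1 column per library. Reads shared by near-identical genes (histone, class I, ribosomal protein, tubulin and Oas families among them), by overlapping genes or by antisense partners could therefore be split or lost in the counting, and values of such genes are uncertain.

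The table held 40757 entries, of which 351 repeated another in symbol and in every count. These held 0.907% of the counts and were removed, which left 40406. A further 82 shared a symbol with another entry but not its counts and were kept. Every symbol was matched to GENCODE mouse release M21 on GRCm38 for gene type, position, GC content and length. Every column mapped to a library by its title. Total counts ran from 28.7 to 40.8 mega-counts per library. Chi-square values per degree of freedom between libraries of 1 group ran from 8.46 to 172, so no library was a repeat of another.

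Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries scaled by TMM, and 1 quasi-likelihood model with a mean for each of the 4 groups was fitted to the 12 libraries, so that all groups shared the estimate of spread. The contrasts were docetaxel against DMSO within each genotype, knockout-labelled against wild type within each treatment, and their interaction, each two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 15538 tested genes within each contrast and called at 0.05. Log2 fold changes are those of the fitted model with edgeR's default prior count, and a prior count of 2 was used for log2 CPM values only. Each standard error is the absolute log2 fold change divided by the square root of its F statistic. The common biological coefficient of variation was 13.2%. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. For genes with few counts in a group, the ratio of summed counts, scaled by library size, has an exact 95% counting interval. Such intervals cover counting error only.

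Gene lists were fixed before the data were examined, as were the contrasts, tests, named-gene rule and most alternatives. Of these, 35 were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives, adjusted over the lists within each contrast. Fry tests whether the genes of a list move, on balance, one way, or in its mixed form in either direction, and does not compare them with other genes. 1 further list, of endothelial markers, had 3 tested members and was not tested as a group. Named genes were Itgb3, Itgav and Itga2b, the 8 largest increases and decreases per contrast (6 for the interaction) among called protein-coding genes with at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups (a condition not applied to the interaction), and up to 4 called members of each list with the largest changes and a mean of at least 5 CPM. Genes of the interaction outside this rule, and the 81 genes used to check the labels, were chosen after their values were seen.

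The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter on low counts, at least 1 CPM in 3 libraries, protein-coding genes only, the 6 libraries of a contrast alone, replicate number as a block, and the omission of each library in turn. Chosen after seeing the data were a lowess correction of each library for GC content (span 0.3), the repeated entries kept, the omission of the 2 libraries richest in Gm23935 of their groups, and the omission of each library in the list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

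The edgeR tests of the 5 contrasts, and the GC correction for docetaxel in wild-type cells, were run on simulated counts. These were drawn from the real means and library sizes, with 200 changed genes in each simulation. DESeq2, limma-voom, the other scalings and the splits were not simulated. For docetaxel in wild-type cells, over 15193 genes, 38.8%, 91.0% and 98.5% of genes with log2 changes of 0.5, 1 and 2 were recovered. For docetaxel in knockout-labelled cells, over 15250 genes, the shares were 34.3%, 92.5% and 100%. For the genotypes under DMSO, over 15188 genes, they were 37.3%, 88.1% and 100%, and after docetaxel, over 15227 genes, 52.2%, 86.6% and 100%. For the interaction, over 15232 genes, they were 8.96%, 65.7% and 100%. Between 1.96% and 6.45% of the simulated calls in these 5 contrasts were false. Genes were drawn independently of each other, and only genes with a mean above 2 CPM were changed. With 915 to 4406 genes called in the real pairwise comparisons, the shares do not measure recovery there. With the GC trends of the real libraries in the simulation of docetaxel in wild-type cells, 19.4%, 91.0% and 100% were recovered over 15203 genes, and 34.3%, 92.5% and 100% over 15228 genes after GC correction, with 2.10% and 6.79% of the calls false.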

Results

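Transcript levels were measured by RNA sequencing in 4T1 cells, a mouse line of triple-negative mammary carcinoma from the BALB/c strain. The cells carried the label wild type or knockout for integrin β3, the product of Itgb3, which pairs with the αv and αIIb subunits to form cell-surface receptors for matrix proteins. Each genotype received either the solvent DMSO or 10 nM docetaxel, a taxane that stabilises microtubules, for 24 h, and was harvested after 48 h in drug-free medium. The 12 libraries formed 4 groups of 3, described in the labels as biological triplicates, and n = 3 libraries for every group mean below. Total gene counts, in mega-counts (M), were 28.7, 29.6 and 32.3 M in the wild-type DMSO libraries and 33.0, 35.9 and 34.6 M in the wild-type docetaxel libraries. They were 31.8, 30.9 and 34.4 M in the knockout-labelled DMSO libraries and 40.8, 35.6 and 31.6 M in the knockout-labelled docetaxel libraries. Between 19840 and 22648 genes were detected per library, and 15538 were tested.

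The first principal component held 32.2% of the variance and separated docetaxel libraries, at 23 to 41.8, from DMSO libraries, at −47.7 to −21.6. The second held 25% and separated wild-type libraries, at 20.01 to 35.5, from knockout-labelled libraries, at −40.6 to −14.3. Gm23935, a feature annotated as a microRNA gene, took 1.62%, 3.98% and 0.435% of the counts in the wild-type DMSO libraries and 0.856%, 0.294% and 1.51% in the knockout-labelled docetaxel libraries. Its share was 0.14% to 0.22% in the other 6 libraries. Another feature, Gm26917, took a larger share in every library, from 7.07% to 11.9% of the counts. Within groups, libraries also differed in the GC content of the transcripts they favoured. This was measured over the 9961 protein-coding genes with a mean log2 CPM above 2. The first axis of within-group variation held 50.2% of that variance. Its gene loadings correlated with transcript GC content across these genes, which are not independent replicates (Spearman's rho 0.645).

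Itgb3 lies on chromosome 11 from 104608000 to 104670476 on the plus strand of GRCm38 (ENSMUSG00000020689.4). Its level was 71.4, 60.1 and 66.1 CPM, normalised counts scaled to a common library total, in the wild-type DMSO libraries and 62.4, 66.7 and 65 CPM in the knockout-labelled DMSO libraries. It was 80.6, 88.7 and 80 CPM in the wild-type docetaxel libraries and 59.3, 64.6 and 63.4 CPM in the knockout-labelled docetaxel libraries. The transcript was therefore not reduced in the knockout-labelled cells under DMSO, with a log2 difference of −0.03 ± 0.08 (SE; edgeR adjusted p = 0.874). After docetaxel it was lower in the knockout-labelled cells by a log2 difference of −0.41 ± 0.08 (edgeR adjusted p = 0.00765). Docetaxel raised Itgb3 in wild-type cells, with a log2 fold change of 0.34 ± 0.08 (edgeR adjusted p = 0.00856). Without wild-type DMSO library 2 and knockout-labelled docetaxel library 3, the libraries of their groups richest in Gm23935, that adjusted p was 0.0563 at a log2 fold change of 0.27. In knockout-labelled cells the docetaxel change of Itgb3 was −0.05 (edgeR adjusted p = 0.725), and the difference between the 2 docetaxel effects did not pass its own test (edgeR adjusted p = 0.294). Because the Itgb3 transcript did not separate the genotypes under DMSO, the cells are called knockout-labelled throughout, and every genotype direction rests on the labels. A count over the whole gene does not separate an intact transcript from one that carries a small deletion, and the way the knockout was made is not given in the sources used here.

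**Figure D1:**
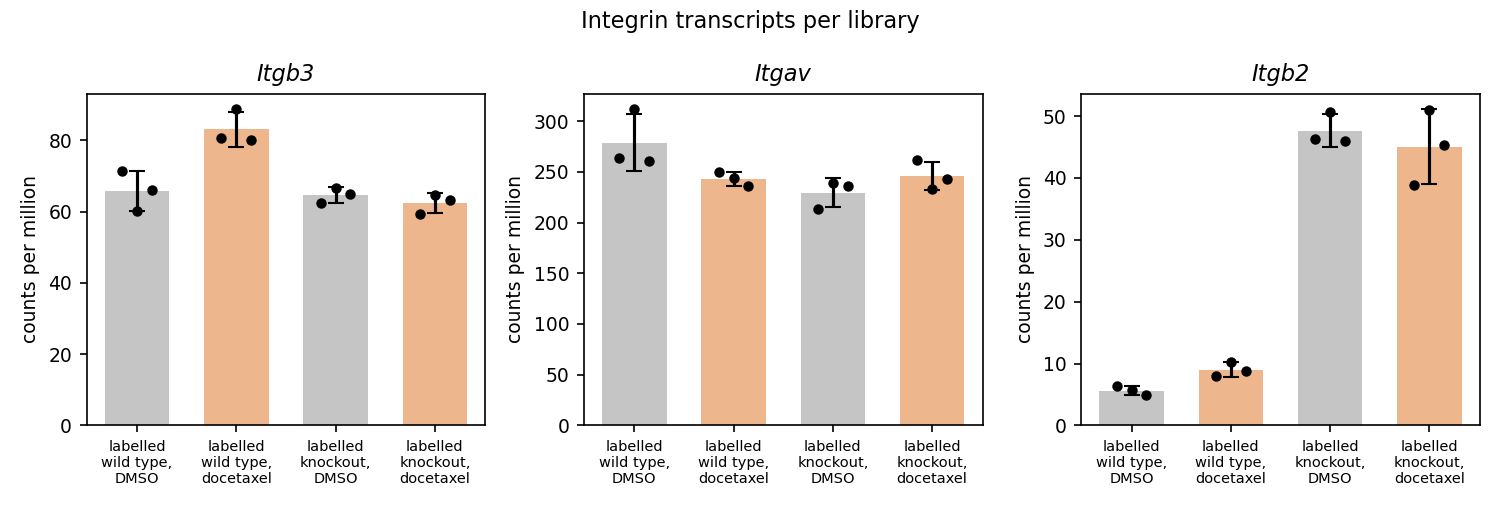
CPM (normalised counts) of integrin subunit genes in the 4 groups, with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. Itgb3 reached 83.1 CPM in wild-type docetaxel libraries and lay between 62.4 and 65.9 CPM in the other 3 groups.

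The αv partner gene Itgav (ENSMUSG00000027087.11) lies on chromosome 2 from 83724397 to 83806916 on the plus strand, and the αIIb partner gene Itga2b (ENSMUSG00000034664.13) on chromosome 11 from 102453297 to 102470122 on the minus strand. Neither passed the test for docetaxel in either genotype (edgeR adjusted p = 0.102 and 0.478 for Itgav, 0.863 and 0.689 for Itga2b). The log2 fold change of Itgav in wild-type cells was −0.20 ± 0.09. For Itga2b the standard errors were 0.37 in wild-type and 0.38 in knockout-labelled cells, so sizeable changes could be missed. Itga2b was low, at 1.82 to 2.97 CPM. Itgav was lower in the knockout-labelled cells under DMSO, with a log2 difference of −0.28 ± 0.09 (edgeR adjusted p = 0.0418). That call was lost without wild-type DMSO library 2 (adjusted p = 0.173) and without knockout-labelled DMSO library 1 (0.187), 2 (0.0691) or 3 (0.0870). The wild-type DMSO library 1 has a free-text description that names the knockout, while its title and genotype label name the wild type. The check used 81 genes called at least 2-fold apart between the genotypes in the docetaxel libraries, with a mean log2 CPM above 2. Over these genes the mean signed log2 CPM of wild-type DMSO library 1 was −0.155. The other wild-type DMSO libraries had −0.190 and −0.297, and the knockout-labelled DMSO libraries lay between 1.28 and 1.35. The docetaxel libraries, in which the genes were chosen and which are therefore no independent reference, lay between −0.231 and −0.178 and between 1.24 and 1.37.

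The effect of docetaxel was first examined in wild-type cells. Nos2, the inducible nitric oxide synthase, rose from 4.82 ± 1.79 to 79.9 ± 27.2 CPM (mean ± SD), and the chemokine gene Ccl2 from 2.77 ± 1.27 to 33.7 ± 4.77 CPM. Acod1, which encodes the enzyme that makes itaconate, rose from 1.41 ± 0.424 to 25.4 ± 5.19 CPM. Of the type I interferon response, DNA replication and ribosome biogenesis genes tested, 36 of 41, 28 of 45 and 22 of 32 rose (adjusted p = 0.373, 0.418 and 0.415 with an estimated correlation). Of the glycolysis and hypoxia, ribosomal protein and replication-dependent histone genes, 26 of 33, 32 of 46 and 17 of 26 fell (adjusted p = 0.326, 0.373 and 0.373 with an estimated correlation).

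Among 30 tested NF-κB targets, cytokine and chemokine genes, 25 rose, 0 fell and 5 did not pass, with 27 rising when adjusted over the list alone. Their median log2 fold change was 1.53 (camera adjusted p = 3.7e-16, and adjusted p = 0.0352 with an estimated correlation). The cytokine gene Il1a rose from 4.39 ± 0.161 to 43.0 ± 2.91 CPM and Lcn2, which encodes the iron-sequestering protein lipocalin 2, from 76.2 ± 11.1 to 639 ± 62.2 CPM. The senescence-associated secretion list, which shares members with the NF-κB list, had 11 of 26 genes risen, 2 fallen and 13 not passed, with the same 11 and 2 counts adjusted over the list alone. It rose as a group (camera adjusted p = 8.55e-05, and adjusted p = 0.0352 with an estimated correlation). Its neutrophil chemokine genes Cxcl1 and Cxcl5 had log2 fold changes of 2.87 ± 0.14 and 2.32 ± 0.21. Of 41 type I interferon response genes, 36 rose, 0 fell and 5 did not pass, with 37 rising when adjusted over the list alone. The list's median log2 fold change was 0.80 (camera adjusted p = 7.34e-14, but adjusted p = 0.373 with an estimated correlation). Oasl1 rose from 51.7 ± 10.7 to 183 ± 23.6 CPM and the chemokine gene Cxcl10 from 34.7 ± 4.64 to 120 ± 15.2 CPM.

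Of 21 genes of MHC class I and antigen processing, 12 rose, 0 fell and 9 did not pass, with 14 rising when adjusted over the list alone. The list rose as a group (camera adjusted p = 1.03e-05, but adjusted p = 0.415 with an estimated correlation). The chaperone gene Calr rose from 264 ± 22.6 to 594 ± 14.5 CPM, and Nlrc5, a transcriptional activator of class I genes, from 15.6 ± 1.63 to 33.3 ± 1.83 CPM. Of 19 matrix protease and inhibitor genes, 10 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00537, but adjusted p = 0.105 with an estimated correlation). The collagenase gene Mmp13 rose from 6.55 ± 1.63 to 27.5 ± 2.61 CPM. Among 13 osteomimicry and bone metastasis genes, a list that includes Mmp13, 8 rose, 0 fell and 5 did not pass, with the same 8 adjusted over the list alone (camera adjusted p = 0.00141, but adjusted p = 0.0999 with an estimated correlation). Csf1, which encodes a macrophage growth factor, rose from 128 ± 10.9 to 240 ± 33.2 CPM. Of 23 immediate-early and heat-shock genes, 10 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00537, but adjusted p = 0.105 with an estimated correlation). Fos rose from 3.02 ± 0.725 to 10.4 ± 1.00 CPM and Egr3 fell from 5.50 ± 1.14 to 2.95 ± 0.430 CPM.

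Of 45 genes of DNA replication and S phase, 28 rose, 0 fell and 17 did not pass, with 30 rising and 1 falling when adjusted over the list alone. Their median log2 fold change was 0.49 (camera adjusted p = 1.67e-07, but adjusted p = 0.418 with an estimated correlation). The cyclin gene Ccne1 rose from 2.70 ± 0.694 to 11.4 ± 0.863 CPM and the origin recognition gene Orc1 from 5.92 ± 2.04 to 13.9 ± 2.29 CPM. Of 32 genes of ribosome biogenesis and MYC targets, 22 rose, 2 fell and 8 did not pass, with 23 and 2 adjusted over the list alone. The list rose as a group (camera adjusted p = 4.56e-06, but adjusted p = 0.415 with an estimated correlation), with Rrp12 at a log2 fold change of 1.29 ± 0.19. Of 46 cytosolic ribosomal protein genes, 0 rose, 32 fell and 14 did not pass, with 37 falling when adjusted over the list alone (camera adjusted p = 2.63e-11, but adjusted p = 0.373 with an estimated correlation). Rpl3 fell from 750 ± 100 to 470 ± 64.3 CPM. Of 26 replication-dependent histone genes, 1 rose, 17 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 4.56e-06, but adjusted p = 0.373 with an estimated correlation). Hist1h2ae fell from 227 ± 24.2 to 117 ± 7.87 CPM.

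Of 33 genes of glycolysis and hypoxia, 2 rose, 26 fell and 5 did not pass, with 27 falling when adjusted over the list alone. Their median log2 fold change was −0.61 (camera adjusted p = 1.03e-10, but adjusted p = 0.326 with an estimated correlation). The glycolytic enzyme gene Aldoc fell from 118 ± 19.4 to 29 ± 7.97 CPM and the carbonic anhydrase gene Car9 from 9.52 ± 2.30 to 2.25 ± 1.12 CPM. Among 28 tubulin and microtubule regulator genes, 9 rose, 3 fell and 16 did not pass, with 10 and 3 adjusted over the list alone, and the list did not pass as a group (camera adjusted p = 0.0806). Tubb6 rose from 117 ± 20.3 to 277 ± 15 CPM and Tuba4a from 76.6 ± 7.33 to 155 ± 8.41 CPM. Of 18 integrin subunit genes, 4 rose, 3 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.603). The β4 subunit gene Itgb4 fell from 319 ± 41.5 to 183 ± 2.35 CPM. The unfolded protein and integrated stress response list was mixed, with 12 of 32 genes risen, 14 fallen and 6 not passed (13 and 14 adjusted over the list alone; camera adjusted p = 0.652). Sdf2l1, an endoplasmic reticulum protein gene, had a log2 fold change of 1.25 ± 0.19, and the stress-induced genes Trib3 and Asns fell from 129 ± 42.3 to 33.0 ± 4.70 CPM and from 163 ± 24.3 to 72.2 ± 5.18 CPM.

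Another 5 lists passed with all 12 libraries and lost their call when 1 library was left out. mTORC1 signalling fell, with 11 of 42 genes risen, 21 fallen and 10 not passed (13 and 22 adjusted over the list alone; camera adjusted p = 0.00653, adjusted p = 0.373 with an estimated correlation, 0.0898 without wild-type DMSO library 1). Collagens fell, with 0 of 18 genes risen, 6 fallen and 12 not passed (1 and 6 adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.415 with an estimated correlation). The collagen value was 0.0615, 0.101 and 0.0530 without wild-type DMSO libraries 1 and 3 and wild-type docetaxel library 1. The epithelial program fell, with 2 of 24 genes risen, 8 fallen and 14 not passed (2 and 8 adjusted over the list alone; camera adjusted p = 0.0232, adjusted p = 0.578 with an estimated correlation), and gave 0.168 and 0.108 without wild-type DMSO library 3 and wild-type docetaxel library 1, and 0.106 with fry. Cholesterol biosynthesis rose, with 9 of 24 genes risen, 1 fallen and 14 not passed (9 and 1 adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.645 with an estimated correlation), and gave 0.0549 and 0.166 without wild-type DMSO libraries 2 and 3, and 0.118 with fry. Mitosis genes rose, with 7 of 44 risen, 1 fallen and 36 not passed (7 and 1 adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.655 with an estimated correlation), and gave 0.361 and 0.108 without wild-type DMSO library 3 and wild-type docetaxel library 2, and 0.118 with fry.

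In all, 4406 of 15538 genes (28.4%) changed in wild-type cells, 2259 higher and 2147 lower with docetaxel, by edgeR's quasi-likelihood test at an adjusted p threshold of 0.05. At least 2-fold changes numbered 579 higher and 234 lower. The libraries of the 2 groups did not overlap for 6288 genes (40.5%), where chance gives 10%. Of 35 lists tested, 17 passed camera, 11 higher and 6 lower. Among the named genes that fell were Mroh6 and Ankrd60, whose wild-type DMSO libraries spread over 37.7 to 609 and 239 to 1257 CPM, with the highest value each time in the library in which Gm23935 took 3.98% of the counts. Among the simulated genes for this comparison, 38.8% with a log2 change of 0.5 and 91.0% with a log2 change of 1 were recovered over 15193 genes. With the GC trends of the real libraries in the simulation, 19.4% and 91.0% were recovered over 15203 genes. Only 200 genes changed in these simulations, against 4406 called here, so the shares do not measure recovery in the real comparison.

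In knockout-labelled cells Nos2 rose with docetaxel from 5.18 ± 1.76 to 116 ± 28.5 CPM, Ccl2 from 1.80 ± 0.126 to 30.4 ± 2.39 CPM, and Chil1, a chitinase-like protein gene, from 2.80 ± 0.426 to 65.2 ± 5.08 CPM. All 41 tested type I interferon response genes rose (adjusted p = 0.143 with an estimated correlation). Ehf, an epithelial transcription factor gene, went from 12 counts over the 3 DMSO libraries to 625 over the 3 docetaxel libraries, a ratio of 45.3 (95% counting interval 25.8 to 88.2). Of the glycolysis and hypoxia, histone and ribosomal protein genes, 27 of 33, 18 of 26 and 14 of 46 fell (adjusted p = 0.182, 0.196 and 0.297 with an estimated correlation). The angiotensin-converting enzyme gene Ace fell from 83.7 ± 1.26 to 27.0 ± 1.70 CPM and the keratin gene Krt15 from 8.17 ± 0.182 to 2.87 ± 1.08 CPM.

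The 41 interferon response genes also all rose when adjusted over the list alone, with a median log2 fold change of 1.73 (camera adjusted p = 3.63e-38, but adjusted p = 0.143 with an estimated correlation). The antiviral gene Oas2 rose from 6.16 ± 1.14 to 62.5 ± 7.54 CPM and Ifi44 from 20.3 ± 5.84 to 128 ± 5.32 CPM. Of the 30 NF-κB targets, cytokine and chemokine genes, 24 rose, 0 fell and 6 did not pass, with 28 rising when adjusted over the list alone. Their median log2 fold change was 2.16 (camera adjusted p = 3.64e-25, and adjusted p = 0.00958 with an estimated correlation). Il1a rose from 12.6 ± 1.35 to 125 ± 29.7 CPM and Ccl20 from 0.734 ± 0.133 to 8.78 ± 1.81 CPM. In the senescence-associated secretion list 12 of 26 genes rose, 2 fell and 12 did not pass, with 13 and 2 adjusted over the list alone (camera adjusted p = 3.64e-06, and adjusted p = 0.00958 with an estimated correlation). Cxcl1 rose from 29.8 ± 0.999 to 292 ± 32.8 CPM. Of the 21 MHC class I and antigen processing genes, 17 rose, 0 fell and 4 did not pass, with 20 rising when adjusted over the list alone (camera adjusted p = 2.95e-11, but adjusted p = 0.196 with an estimated correlation). B2m, the light chain of class I molecules, rose from 357 ± 28.8 to 745 ± 48.8 CPM.

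Matrix protease and inhibitor genes rose in 9 of 19 cases, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 3.61e-05, and adjusted p = 0.0198 with an estimated correlation). Mmp13 rose from 3.16 ± 0.197 to 19.3 ± 2.42 CPM and the inhibitor gene Serpine2 from 33.4 ± 2.96 to 71.2 ± 8.14 CPM. Of 25 apoptosis regulators, 9 rose, 0 fell and 16 did not pass, with 11 rising when adjusted over the list alone (camera adjusted p = 0.0113, but adjusted p = 0.135 with an estimated correlation). The members that rose included genes with opposite known roles, the death receptor gene Fas, from 5.14 ± 0.353 to 17.5 ± 0.530 CPM, and the inhibitor of apoptosis gene Birc3, from 16.9 ± 1.65 to 30.4 ± 1.37 CPM. In the unfolded protein and integrated stress response list 9 of 32 genes rose, 2 fell and 21 did not pass, with the same 9 and 2 adjusted over the list alone (camera adjusted p = 0.0113, but adjusted p = 0.269 with an estimated correlation). Atf3 rose from 6.27 ± 0.326 to 18.5 ± 0.749 CPM and the chaperone gene Hyou1 from 122 ± 12.3 to 210 ± 4.26 CPM.

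Of the 33 glycolysis and hypoxia genes, 1 rose, 27 fell and 5 did not pass, with 2 and 27 adjusted over the list alone (camera adjusted p = 9.11e-15, but adjusted p = 0.182 with an estimated correlation). Ankrd37 fell from 9.39 ± 0.645 to 1.80 ± 0.286 CPM and the mitophagy receptor gene Bnip3 from 59.4 ± 10.1 to 23 ± 1.28 CPM. Of the 26 histone genes, 0 rose, 18 fell and 8 did not pass, with 1 rising and 22 falling when adjusted over the list alone (camera adjusted p = 6.41e-09, but adjusted p = 0.196 with an estimated correlation). Hist1h3g fell from 284 ± 39.9 to 174 ± 14 CPM. Of the 46 ribosomal protein genes, 0 rose, 14 fell and 32 did not pass, with 37 falling when adjusted over the list alone (camera adjusted p = 2.95e-11, but adjusted p = 0.297 with an estimated correlation). In mTORC1 signalling 3 of 42 genes rose, 13 fell and 26 did not pass, with 3 and 14 adjusted over the list alone (camera adjusted p = 0.0154, but adjusted p = 0.297 with an estimated correlation), and the glucose transporter gene Slc2a1 fell from 156 ± 7.45 to 80.1 ± 4.18 CPM. The DNA replication list did not pass (camera adjusted p = 0.191), with 4 of 45 genes risen, 0 fallen and 41 not passed, and 2 rising when adjusted over the list alone. Ribosome biogenesis genes did not pass either (camera adjusted p = 0.124), with 3 of 32 risen, 2 fallen and 27 not passed, and the same counts adjusted over the list alone. Tubulin and microtubule regulator genes rose in 5 of 28 cases and 1 fell, with 22 not passed and 6 and 2 adjusted over the list alone (camera adjusted p = 0.142). Tubb6 rose with a log2 fold change of 0.58 ± 0.13.

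Another 5 lists passed and lost their call when 1 library was left out. Osteomimicry genes rose in 3 of 13 cases, 0 fell and 10 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.182 with an estimated correlation), and mitosis genes in 3 of 44 cases, 0 fell and 41 did not pass (2 and 0 adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.646 with an estimated correlation). Each gave 0.0686 without knockout-labelled DMSO library 2, and mitosis genes 0.0865 after GC correction and 0.181 with fry. NRF2 targets rose in 5 of 23 cases, 0 fell and 18 did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.182 with an estimated correlation), and gave 0.0745 and 0.0598 without knockout-labelled DMSO library 2 and docetaxel library 2. Lysosome and autophagy genes rose in 7 of 29 cases, 2 fell and 20 did not pass (8 and 3 adjusted over the list alone; camera adjusted p = 0.0310, adjusted p = 0.575 with an estimated correlation), and gave 0.0772 and 0.0566 without knockout-labelled docetaxel libraries 2 and 3. The mitochondrially encoded genes had 1 of 13 risen, 0 fallen and 12 not passed (0 and 0 adjusted over the list alone; camera adjusted p = 0.0319, adjusted p = 0.646 with an estimated correlation). That list gave 0.0821 and 0.0686 without knockout-labelled DMSO libraries 1 and 2, 0.277 and 0.0599 without docetaxel libraries 1 and 3, 0.0619 after GC correction and 0.253 with fry.

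In all, 2499 genes (16.1%) changed in knockout-labelled cells by edgeR, 1412 higher and 1087 lower, of which 485 and 112 changed at least 2-fold. Higher genes made up 56.5% of these calls, and 45.3% of 2613 calls when libraries were scaled by their upper quartile. The groups did not overlap for 5862 genes (37.7%, where chance gives 10%), and 16 lists passed camera, 12 higher and 4 lower. Fold changes in this comparison correlated with GC content (Spearman's rho −0.288). That value is across the 9961 protein-coding genes with a mean log2 CPM above 2, which are not independent replicates. The number of changed genes was 1311 without DMSO library 2, 1458 without DMSO library 3, 1616 without docetaxel library 1 and 1500 without docetaxel library 3 of the knockout-labelled cells.

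The docetaxel effects in the 2 genotypes, which share no library, were then compared across the 15538 genes. Genes called in both numbered 1815, of which 1004 rose in both and 798 fell in both, against 205 and 150 for independent lists, and 13 went opposite ways. At least 2-fold changes in the same direction in both genotypes were 298 increases, among them Nos2, Ccl2, Acod1, Chil1 and Il1a, and 49 decreases, among them Aldoc and Ankrd37. Fold changes correlated with a Pearson's r of 0.633 (jackknife SE 0.0658) and a Spearman's rho of 0.581 across genes, which are not independent replicates.

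**Figure D2:**
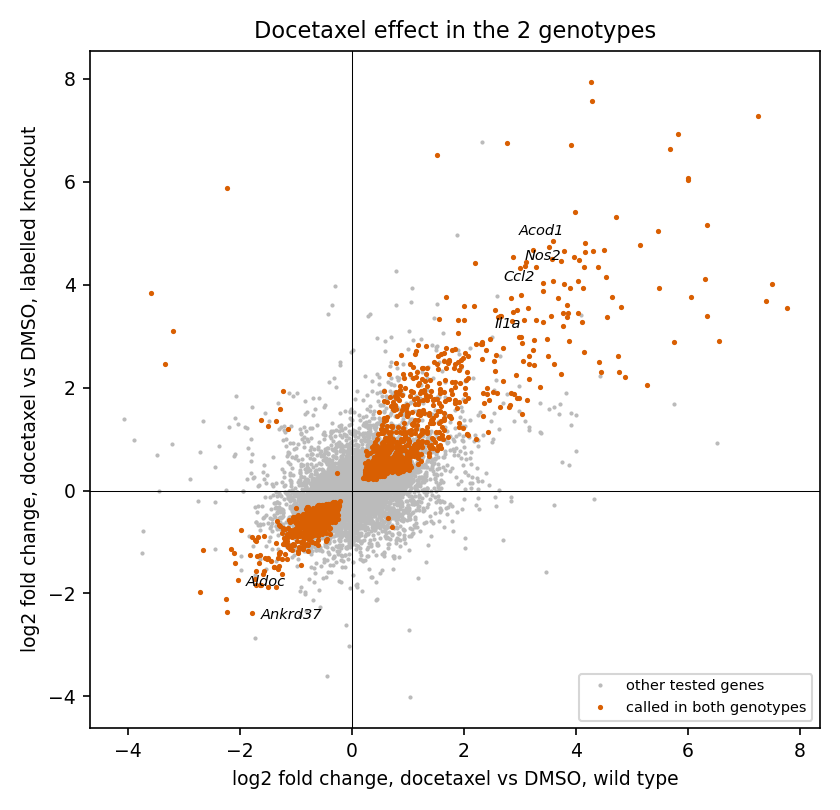
Log2 fold change of docetaxel against DMSO for each tested gene, in wild-type cells on the horizontal axis and knockout-labelled cells on the vertical axis; each point is 1 gene, and coloured points passed the edgeR test in both genotypes. Of the 1815 coloured genes, 1004 lie in the upper right and 798 in the lower left.

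Knockout-labelled and wild-type cells were compared under DMSO to find differences present without the drug. All 41 type I interferon response genes were lower in the knockout-labelled cells, as were 17 of 21 genes of MHC class I and antigen processing (adjusted p = 0.587 with an estimated correlation for each list). Nlrc5 was at 2.24 ± 0.359 CPM against 15.6 ± 1.63 CPM in wild-type cells, and Ifi44 at 20.3 ± 5.84 against 92.9 ± 24.3 CPM. Some genes were close to absent in one genotype. Dsc2, a desmosomal cadherin gene, had 5 counts over the 3 knockout-labelled libraries and 1600 over the 3 wild-type libraries, a ratio of 351 (150 to 1084), and the claudin gene Cldn7 was at 0.0741 ± 0.0499 against 8.95 ± 0.491 CPM. Ap1m2, an epithelial clathrin adaptor gene, had 3 counts over the wild-type libraries and 1414 over the knockout-labelled libraries, a ratio of 429 (147 to 2084). The intervals are 95% and cover counting error only. The epithelial program list of 24 tested genes, Cldn7 among them, did not pass as a group under DMSO (camera adjusted p = 0.340).

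The mechanosensitive channel gene Piezo2 was at 0.174 ± 0.101 CPM in knockout-labelled and 13.2 ± 5.23 CPM in wild-type cells, the kinesin gene Kif21b at 1.12 ± 0.333 and 35.4 ± 5.19 CPM, and the lactate dehydrogenase gene Ldhb at 0.254 ± 0.133 and 5.70 ± 0.298 CPM. In the other direction, the transcytosis gene Mal2 was at 22.7 ± 2.29 CPM in knockout-labelled and 0.285 ± 0.106 CPM in wild-type cells, Iqgap2 at 14.8 ± 0.240 and 0.869 ± 0.157 CPM, and the myelin protein gene Pmp22 at 33.1 ± 0.339 and 1.95 ± 0.959 CPM. Of the 18 integrin subunit genes, 3 were higher, 3 lower and 12 did not pass, with the same 3 and 3 adjusted over the list alone (camera adjusted p = 0.853). The β2 subunit gene Itgb2, typical of leukocytes, was at 47.6 ± 2.63 CPM in knockout-labelled and 5.62 ± 0.734 CPM in wild-type cells, and Itgb6 at 6.34 ± 1.44 and 17.7 ± 4.70 CPM. Of 6 macrophage and leukocyte markers, 0 passed in either direction, also when adjusted over the list alone (camera adjusted p = 0.656). Serpine2 was at 33.4 ± 2.96 CPM in knockout-labelled and 3.20 ± 0.724 CPM in wild-type cells, and the drug efflux pump gene Abcg2 at 5.21 ± 0.521 and 1.31 ± 0.380 CPM. Their lists, matrix proteases and inhibitors and drug efflux, did not pass as groups (camera adjusted p = 0.101 and 0.649).

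The interferon list had a median log2 difference of −1.09, with all 41 genes lower adjusted over the list alone (camera adjusted p = 1.17e-26, but adjusted p = 0.587 with an estimated correlation). Of the 21 MHC class I and antigen processing genes, 0 were higher, 17 lower and 4 did not pass, with 18 lower when adjusted over the list alone (camera adjusted p = 1.88e-09, but adjusted p = 0.587 with an estimated correlation). In the unfolded protein and integrated stress response list 0 of 32 genes were higher, 15 lower and 17 did not pass, with the same 15 adjusted over the list alone (camera adjusted p = 2.72e-06, but adjusted p = 0.330 with an estimated correlation). Herpud1 was at 19.4 ± 1.35 CPM in knockout-labelled and 47.0 ± 2.70 CPM in wild-type cells, and Chac1 at 21.3 ± 2.38 and 44.4 ± 4.56 CPM. Of 29 lysosome and autophagy genes, 1 was higher, 10 were lower and 18 did not pass, with 1 and 13 adjusted over the list alone (camera adjusted p = 3.76e-05, but adjusted p = 0.600 with an estimated correlation). Gpnmb had a log2 difference of −1.66 ± 0.10. Ribosome biogenesis genes were higher in 12 of 32 cases, 0 were lower and 20 did not pass, with 18 higher when adjusted over the list alone (camera adjusted p = 4.64e-07, but adjusted p = 0.665 with an estimated correlation). DNA replication genes were higher in 14 of 45 cases, 1 was lower and 30 did not pass, with 24 and 1 adjusted over the list alone (camera adjusted p = 6.16e-07, but adjusted p = 0.665 with an estimated correlation and 0.0668 with fry). Ccne1 was at 5.46 ± 0.787 CPM in knockout-labelled and 2.70 ± 0.694 CPM in wild-type cells. Cholesterol biosynthesis genes were higher in 3 of 24 cases, 0 were lower and 21 did not pass, with the same 3 adjusted over the list alone (camera adjusted p = 0.0203, adjusted p = 0.720 with an estimated correlation). That list gave 0.0692 and 0.342 without wild-type DMSO libraries 2 and 3, 0.123 and 0.0585 without knockout-labelled DMSO libraries 1 and 3, and 0.211 with fry.

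In all, 2454 genes (15.8%) differed under DMSO by edgeR, 1025 higher and 1429 lower in the knockout-labelled cells, of which 238 and 355 differed at least 2-fold. The groups did not overlap for 5067 genes (32.6%, where chance gives 10%), and 7 of the 35 lists passed camera. The number of genes was 1581 without wild-type DMSO library 2, and 1264 and 1566 without knockout-labelled DMSO libraries 1 and 3. It was 1267 without the libraries of wild-type DMSO and knockout-labelled docetaxel richest in Gm23935.

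After docetaxel, the comparison of the genotypes asks which differences are present in cells that have both been through the drug. Some genes near absent in one genotype under DMSO were so after docetaxel too. Dsc2 had 14 counts over the 3 knockout-labelled libraries and 1162 over the 3 wild-type libraries, a ratio of 86.2 (51.2 to 158), and Ap1m2 had 2 counts in wild-type and 1398 in knockout-labelled libraries, a ratio of 673 (186 to 5560). The MHC class I gene H2-D1 was at 465 ± 63.5 CPM in knockout-labelled and 840 ± 153 CPM in wild-type cells. Itgb2 was at 45.1 ± 6.02 CPM in knockout-labelled and 8.99 ± 1.20 CPM in wild-type cells, and Lcn2 was 1.57-fold as high in the knockout-labelled cells (log2 difference 0.65 ± 0.11).

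Mal2 was at 30.8 ± 4.96 CPM in knockout-labelled and 0.330 ± 0.0309 CPM in wild-type cells, Pmp22 at 48.3 ± 1.99 and 2.79 ± 0.572 CPM, and Cldn7 at 0.139 ± 0.0428 and 7.81 ± 0.941 CPM. The epithelial program list, which includes Cldn7, did not pass as a group after docetaxel (camera adjusted p = 0.0768). Epsti1 was at 0.462 ± 0.0842 CPM in knockout-labelled and 8.02 ± 2.02 CPM in wild-type cells. Of the 21 MHC class I and antigen processing genes, 0 were higher, 8 lower and 13 did not pass, with 15 lower when adjusted over the list alone (camera adjusted p = 7.17e-09, but adjusted p = 0.605 with an estimated correlation). Nlrc5 was at 10.2 ± 0.793 against 33.3 ± 1.83 CPM. Of the 41 interferon response genes, 0 were higher, 4 lower and 37 did not pass, with 12 lower when adjusted over the list alone (camera adjusted p = 2.99e-06, but adjusted p = 0.838 with an estimated correlation and 0.3002 with fry). Herc6 was at 31.3 ± 1.47 against 49.0 ± 5.37 CPM. Of the 29 lysosome and autophagy genes, 0 were higher, 8 lower and 21 did not pass, with 9 lower when adjusted over the list alone (camera adjusted p = 7.97e-05, but adjusted p = 0.605 with an estimated correlation). The cathepsin gene Ctsb was at 482 ± 4.37 against 664 ± 13.3 CPM. Of the 18 integrin subunit genes, 2 were higher, 2 lower and 14 did not pass, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.737). Of the 23 immediate-early and heat-shock genes, 1 was higher, 3 were lower and 19 did not pass, with 1 and 7 adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.537 with an estimated correlation, 0.0794 without knockout-labelled docetaxel library 1). Fos was at 19.7 ± 1.45 CPM in knockout-labelled and 10.4 ± 1.00 CPM in wild-type cells, and Egr1 at 14.9 ± 1.60 and 26.8 ± 5.56 CPM.

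In all, 915 genes (5.89%) differed after docetaxel by edgeR, 389 higher and 526 lower in the knockout-labelled cells, of which 162 and 139 differed at least 2-fold. The groups did not overlap for 3896 genes (25.1%, where chance gives 10%), and 4 of the 35 lists passed camera. The number of genes was 609, 551 and 467 without wild-type docetaxel libraries 1, 2 and 3 and 527 without knockout-labelled docetaxel library 3, the library of its group richest in Gm23935. It was 565 when wild-type DMSO library 2 was left out as well.

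The genotype differences under the 2 treatments share no library. Genes called under both numbered 675, of which 280 were higher and 390 lower in the knockout-labelled cells under both, against 25.7 and 48.4 for independent lists, and 5 went opposite ways. At least 2-fold differences in the same direction under both treatments were found for 120 higher genes, among them Ap1m2, Mal2, Pmp22 and Itgb2, and 110 lower genes, among them Dsc2, Cldn7, Piezo2 and Kif21b. Pearson's r was 0.568 (jackknife SE 0.0525) and Spearman's rho 0.376 across genes, which are not independent replicates.

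**Figure D3:**
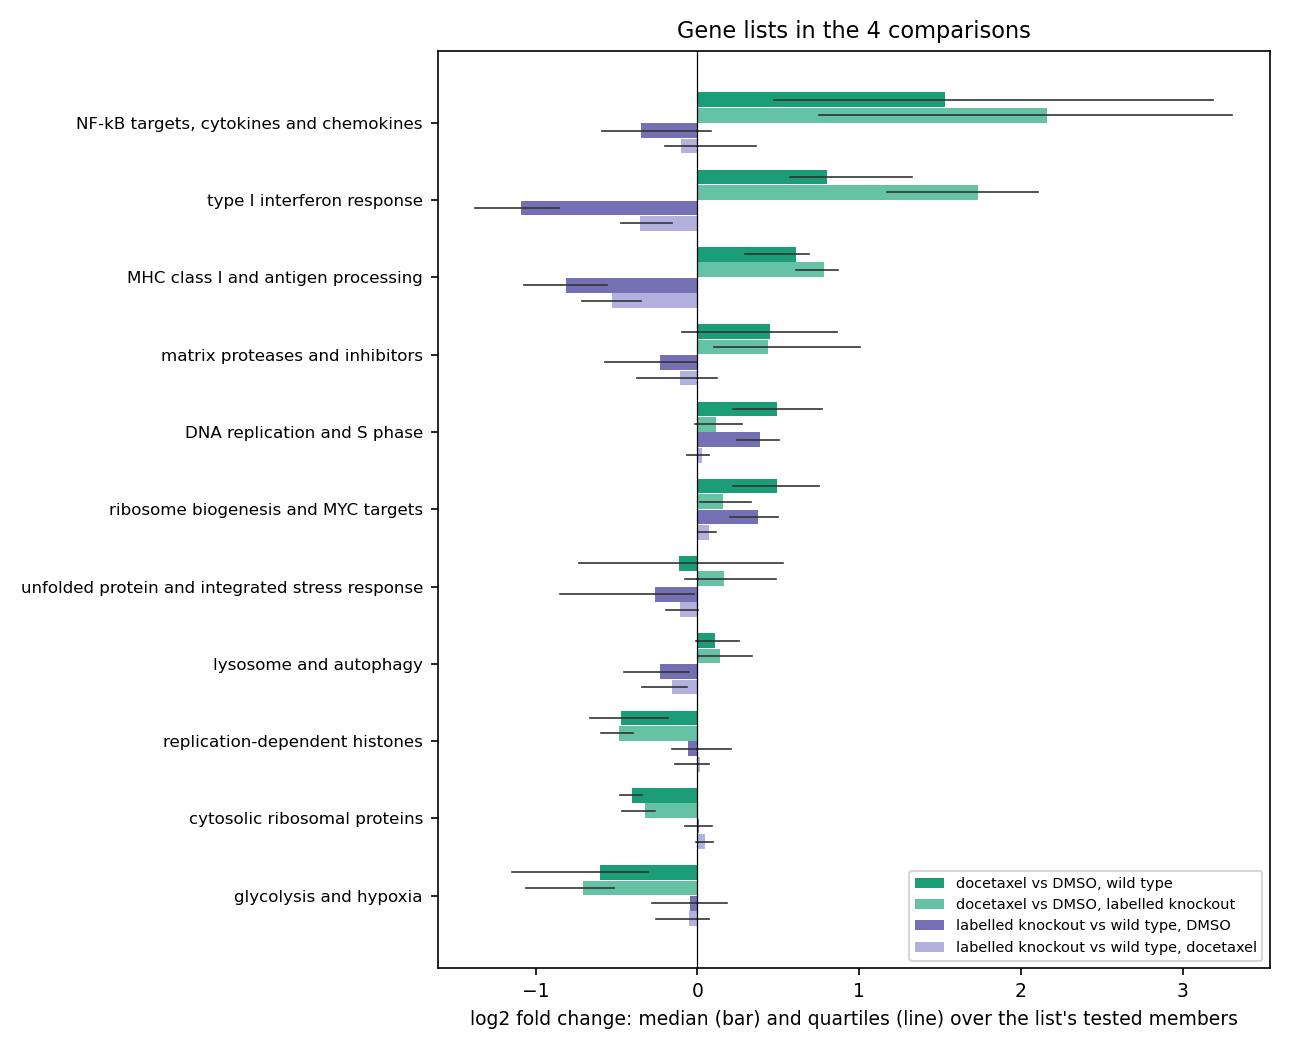
Median log2 fold change (bars) and interquartile range over the tested members (lines) of 11 gene lists in the 4 pairwise comparisons, with 3 libraries per group. The interferon list had medians of 0.80 and 1.73 with docetaxel in wild-type and knockout-labelled cells, and −1.09 in the genotype comparison under DMSO.

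The interaction tested whether the docetaxel effect differed between the genotypes. Ifi27, an interferon-induced gene, went from 161 ± 10.5 to 141 ± 3.41 CPM with docetaxel in wild-type cells and from 81.0 ± 8.59 to 188 ± 8.41 CPM in knockout-labelled cells. Lgals9, which encodes galectin 9, went from 154 ± 37.5 to 245 ± 27.7 CPM in wild-type cells and from 34.6 ± 6.13 to 165 ± 12.1 CPM in knockout-labelled cells. Asns, the asparagine synthetase gene, was at 163 ± 24.3 CPM in the wild-type DMSO group and at 72.2 ± 5.18, 82.2 ± 3.71 and 79.1 ± 2.94 CPM in the wild-type docetaxel, knockout-labelled DMSO and knockout-labelled docetaxel groups. The stress-response transcription factor gene Atf4 was at 276 ± 26.5 CPM there and at 140 ± 7.94, 137 ± 11.9 and 135 ± 15.4 CPM in the same 3 groups.

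**Figure D4:**
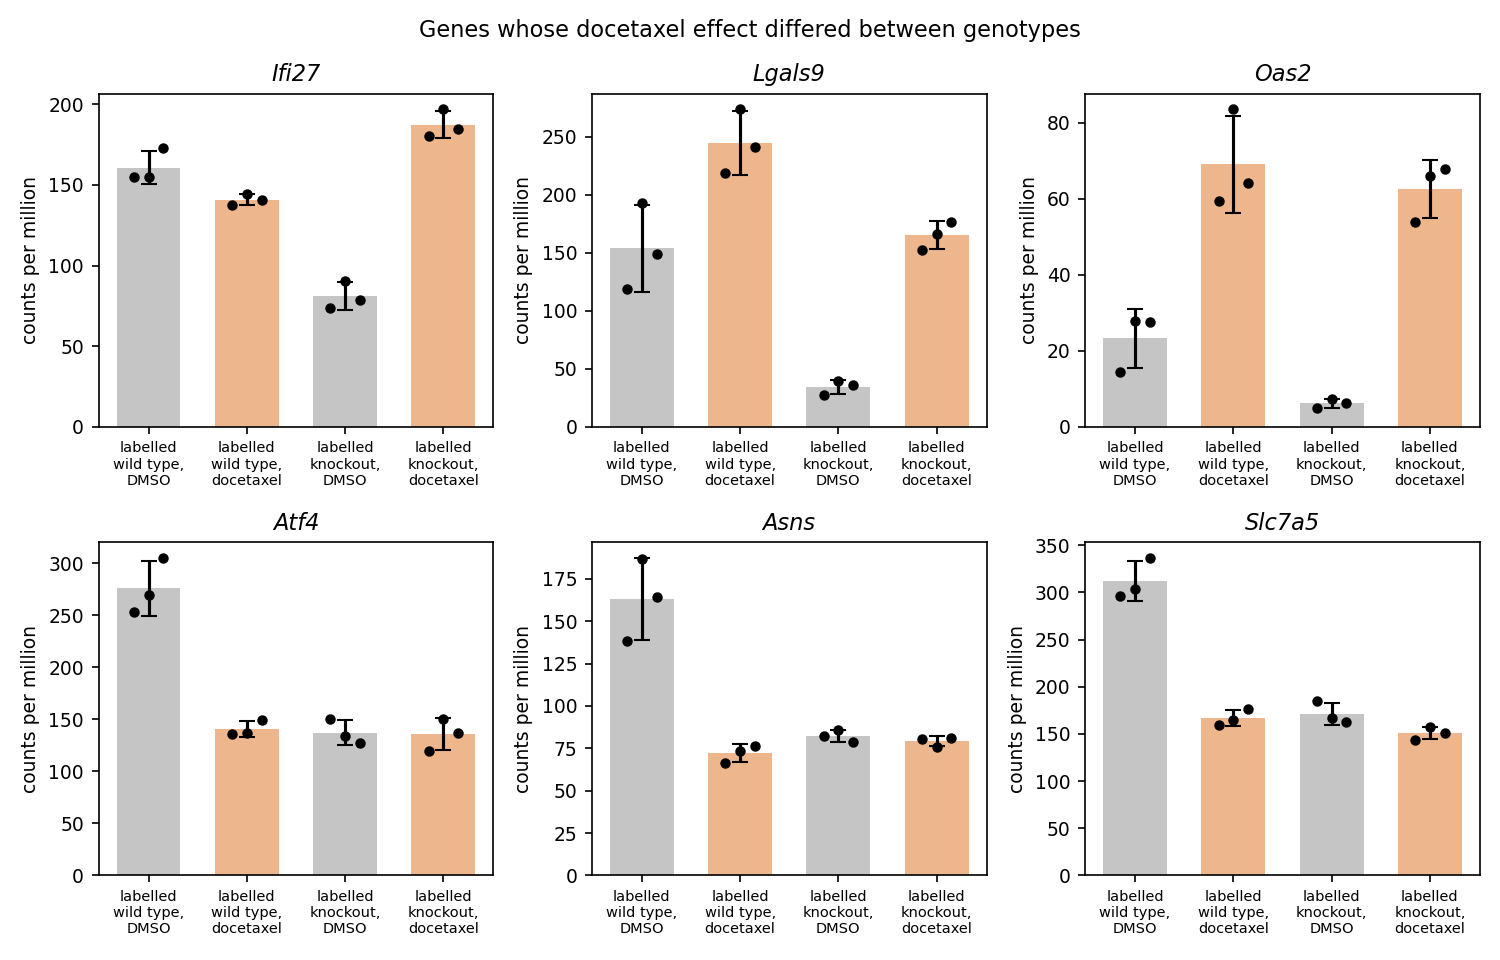
CPM (normalised counts) in the 4 groups of genes that passed the interaction test, with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. Asns and Atf4 are highest in wild-type DMSO libraries, and Ifi27 ranges from 81.0 CPM in knockout-labelled DMSO to 188 CPM in knockout-labelled docetaxel libraries.

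Over all 15538 genes, 17 passed the interaction test by edgeR, 14 with a more positive docetaxel effect in the knockout-labelled cells and 3 with a more negative one. An unadjusted p under 0.05 was found for 1714 genes. The number that passed was 154 with DESeq2, 8 with limma-voom, 421 with no filter on low counts and 38 with GC correction. The log2 difference between the docetaxel effects was 1.4 ± 0.12 for Ifi27 (edgeR adjusted p = 0.000235) and 1.12 ± 0.14 for Asns (edgeR adjusted p = 0.00856). The antiviral gene Oas2 (1.78), Sp100 (1.22) and Nlrc5 (1.09) passed in the same direction, as did the amino acid transporter genes Slc1a4 (0.76) and Slc7a5 (0.72). Clu (−1.19), the lactoferrin gene Ltf (−1.55) and Nlrp10 (−1.80) passed in the opposite direction. Another 4 were features annotated as microRNA genes, with Gm23935 at 5.79. Gm25911, another of them, was at 410 ± 330 CPM in wild-type DMSO and 287 ± 188 CPM in knockout-labelled docetaxel libraries. The protein-coding gene Ppp1r14a (2.70, edgeR adjusted p = 0.04998) was also highest in these 2 groups, at 82.0 ± 38.1 and 67.7 ± 23.3 CPM. It was at 32.2 ± 11.9 and 26.5 ± 4.72 CPM in wild-type docetaxel and knockout-labelled DMSO libraries. Ppp1r14a passed in 3 of the 12 omissions of 1 library, with an edgeR adjusted p of 0.0748 without wild-type DMSO library 2. The interaction fold changes correlated with GC content (Spearman's rho −0.315). That value is across the 9961 protein-coding genes with a mean log2 CPM above 2, which are not independent replicates. Ifi27 and Gm24270 passed in each of the 12 omissions of 1 library, and Asns in 10, with adjusted p of 0.0645 and 0.0504 without knockout-labelled DMSO library 3 and docetaxel library 3. The other 14 passed in 2 to 7 omissions. Lgals9 gave 0.0846 and 0.0564 without wild-type docetaxel libraries 1 and 3, 0.0540 and 0.0756 without knockout-labelled DMSO libraries 1 and 3, and 0.0778 without knockout-labelled docetaxel library 3. Atf4 gave 0.1003, 0.0871 and 0.0558 without wild-type docetaxel libraries 1, 2 and 3, 0.0843 and 0.0815 without knockout-labelled DMSO libraries 2 and 3, and 0.107 without knockout-labelled docetaxel library 3. The number of genes was 431 and 45 without wild-type DMSO libraries 1 and 3, and 3, 6 and 3 without wild-type docetaxel libraries 1, 2 and 3. It was 5, 5 and 2 without knockout-labelled DMSO libraries 1, 2 and 3, 2 without knockout-labelled docetaxel library 3, and 4 without the 2 libraries richest in Gm23935.

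As groups, 8 of the 35 lists passed camera for the interaction, and none of the 8 passed with an estimated correlation or with fry, where the lowest adjusted p, that of the stress response list, was 0.0609. The interferon response list had a median log2 difference of 0.74 (camera adjusted p = 4.71e-24, but adjusted p = 0.453 with an estimated correlation), with 1 of 41 genes passing singly, 0 negative, and 30 positive when adjusted over the list alone. The stress response list had a median of 0.28 (camera adjusted p = 0.000287, but adjusted p = 0.443 with an estimated correlation), with Asns and Atf4 the 2 of 32 genes passing singly, and 12 positive and 1 negative when adjusted over the list alone. DNA replication, ribosome biogenesis and cholesterol biosynthesis had medians of −0.37 (camera adjusted p = 6.17e-09), −0.32 (8.87e-07) and −0.34 (7.81e-07), with adjusted p = 0.628, 0.628 and 0.621 with an estimated correlation. No gene of these 3 lists, of 45, 32 and 24 tested, passed singly by edgeR, and adjusted over the list alone 1 ribosome biogenesis gene was negative. The same lists passed camera in both pairwise comparisons that use the wild-type DMSO libraries. With docetaxel in knockout-labelled cells camera gave adjusted p = 0.191, 0.124 and 0.142, and between genotypes after docetaxel 0.902, 0.407 and 0.0675. The results of each list rest in part on the same wild-type DMSO libraries and do not count as separate results. The ligand and matrix list of 13 genes (median −0.19), MHC class I and antigen processing (0.18) and the NF-κB list (0.22) each had a camera adjusted p = 0.0447, and adjusted p = 0.443, 0.857 and 0.668 with an estimated correlation. Singly 0 of 13, 1 of 21 (Nlrc5) and 0 of 30 of their genes passed, and adjusted over the list alone 0 positive and 3 negative, 1 and 1, and 0 and 0. Each of these 3 calls was lost in 7 of the 12 omissions of 1 library, and after GC correction the ligand list gave 0.0658 and the NF-κB list 0.0571. The ligand list reached 0.0504 and 0.0930 without wild-type DMSO libraries 1 and 2, 0.0966 and 0.0548 without wild-type docetaxel libraries 2 and 3, 0.102 without knockout-labelled DMSO library 3, and 0.0716 and 0.0576 without knockout-labelled docetaxel libraries 1 and 3. The MHC class I list reached 0.373 without wild-type DMSO library 3, 0.374 and 0.0548 without wild-type docetaxel libraries 1 and 3, 0.157 and 0.0945 without knockout-labelled DMSO libraries 1 and 3, and 0.374 and 0.116 without knockout-labelled docetaxel libraries 2 and 3. The NF-κB list reached 0.101 and 0.0760 without wild-type DMSO libraries 2 and 3, 0.170 without wild-type docetaxel library 1, 0.106 and 0.193 without knockout-labelled DMSO libraries 1 and 3, and 0.0716 and 0.0809 without knockout-labelled docetaxel libraries 1 and 3.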

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

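The test of the stress genes was chosen only after its result was seen, as were the comparison of the split genes with the docetaxel effect, the GC-corrected values as an alternative and the omission of the libraries richest in Gm23935. The 17 genes and 8 gene lists given first were picked out because the docetaxel effect differed between the genotypes by the interaction test.

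The log2 differences of the docetaxel effect, knockout-labelled minus wild type, were 7.42 for Gm25911, 6.29 for Gm24270, 5.79 for Gm23935 and 2.75 for Gm24245, all annotated as microRNA genes. For protein-coding genes they were 2.70 for Ppp1r14a, 1.78 for Oas2, 1.59 for Lgals9, 1.4 for Ifi27, 1.22 for Sp100, 1.12 for Asns, 1.09 for Nlrc5, 0.96 for Atf4, 0.76 for Slc1a4, 0.72 for Slc7a5, −1.19 for Clu, −1.55 for Ltf and −1.80 for Nlrp10. The median log2 differences of the gene lists were 0.74 for type I interferon response, 0.28 for the unfolded protein and integrated stress response, 0.22 for NF-κB targets, 0.18 for MHC class I and antigen processing, −0.19 for αvβ3 ligands and matrix, −0.32 for ribosome biogenesis, −0.34 for cholesterol biosynthesis and −0.37 for DNA replication.

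For the 17 genes with an interaction, a GC difference between libraries as the whole source is argued against by the correction for GC content, after which 94.1% (16 of 17) still passed and their median size was 97.9% of the original. A single library as the source is argued against by the sizes, since the lowest median over the 12 omissions of 1 library was 1.39 (without wild-type DMSO library 2), against 1.55 with all libraries, although the number of calls moved from 2 to 431 with the library left out. Of 100 splits that redrew the treatment labels within each genotype, 2 gave at least 17 genes, the real one included, and the highest other gave 160. A count several times the real one points to a structure of the samples, here the docetaxel effect, since that split exchanges the treatments of all knockout-labelled libraries and 158 of its 160 genes were called for docetaxel in those cells with the opposite sign, which keeps this test from being a clean measure of chance. Each of the 17 was also called between the genotypes under DMSO by edgeR. Of the protein-coding genes, only Ifi27, Nlrc5, Ltf and Nlrp10 were called between genotypes after docetaxel (edgeR adjusted p = 0.00947, 6.15e-07, 0.000211 and 0.0225). For the other protein-coding genes, the genotypes differed under DMSO with no call after docetaxel. A genotype-dependent drug response stays open as a hypothesis, as does a difference between culture dishes of 1 group. For the 4 microRNA features, uneven removal of abundant RNA stays open too, and Ppp1r14a shared their group pattern. Neither the dish difference nor the uneven removal was tested.

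The second pattern is the stress response genes within those 17. A candidate explanation is that the wild-type DMSO cultures were under higher stress at harvest than the other 3 groups. Over Atf4 and Asns the median log2 difference of knockout-labelled against wild-type cells was −0.998 under DMSO and 0.04 after docetaxel, as that explanation needs. These are the genes in which the pattern was seen, so the test does not decide it, and medium, density or harvest of those dishes cannot be told apart from genotype and treatment here.

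The third pattern is the 230 genes at least 2-fold apart between the genotypes under both treatments. Broad copy-number differences between the lines as the whole source for the set are argued against by the 10 nearest tested neighbours of each gene. Their median log2 difference in the gene's direction was 0.0405 (95% bootstrap interval 0.0144 to 0.0648), far below the size of the differences. A gain or loss of only a few genes would not move a median over 10 neighbours, so such changes stay open. The bootstrap interval lies above 0, and a smaller contribution of broad changes stays open on chromosomes 3, 8, 14 and 18. Of their tested protein-coding genes, 12 of 598, 13 of 687, 14 of 424 and 14 of 311 are in the set. Among all tested genes, 230 of 15538 are. The share was highest on chromosome 18 among these chromosomes, and the counts were not split by direction. In the same order, the median log2 differences of protein-coding genes under DMSO were −0.27, −0.16, −0.26 and −0.27. After GC correction 100% of the 230 were called under both treatments. The set was chosen for calls and 2-fold differences under both, which left little room for a loss. Across the 9961 protein-coding genes with a mean log2 CPM above 2, which are not independent replicates, log2 differences correlated with GC content. The directions were opposite under DMSO and after docetaxel (Spearman's rho 0.178 and −0.127). That argues against GC differences between libraries as the whole source of a set that goes the same way under both. Divergence of separately grown lines or clones may contribute beside the genotype label itself, and was not tested, and the number of lines or clones behind each label is not given in the sources used here.

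With 6 libraries there are 10 splits, too few for a share under 0.05. The real split gave 4406 and 2499 genes for docetaxel in wild-type and knockout-labelled cells. It gave 2454 and 915 for the genotypes under DMSO and after docetaxel. In each case it was the only 1 of the 10 with as many genes, and the highest other split gave 0. Each other split puts libraries from both compared groups on each side, so a real difference adds to the spread within the sides. Low counts in the other splits therefore do not measure chance, and no conclusion is drawn from them.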

How the results depend on the processing

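The GC correction, the omission of the 2 libraries richest in Gm23935, the repeated entries kept, the 6-library fits of the correlations and the list tests without 1 library were chosen only after results were seen. No named gene past the threshold and no list that passed camera changed direction under the alternatives run for it. The majority of calls did: with upper-quartile scaling 48.0% (wild type) and 45.3% (knockout-labelled) of the docetaxel calls were higher, with DESeq2 49.7% in wild-type cells, against 51.3% and 56.5%, and without wild-type DMSO library 1 210 of 431 interaction genes were positive, against 14 of 17. The number of genes for docetaxel in wild-type cells, and the numbers with at least 2-fold changes in the 4 pairwise comparisons, stayed within 1.5 times under every alternative run. Unless stated, the cause was not tested.

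Without 1 library at a time, the number of genes ranged from 1311 to 2739 for docetaxel in knockout-labelled cells, from 1264 to 3273 for the genotypes under DMSO, from 467 to 729 for the genotypes after docetaxel and from 2 to 431 for the interaction (2 to 133 at least 2-fold). Without the 2 libraries richest in Gm23935 it was 1267 for the genotypes under DMSO, 565 after docetaxel and 4 for the interaction (4 at least 2-fold). The 17 interaction genes, of which 14 were at least 2-fold, became 154 (72) with DESeq2, 8 (6) with limma-voom, 421 (152) with no filter on low counts and 38 (26) with GC correction. DESeq2 and the unfiltered fit kept all 17. With protein-coding genes only, 8 of the 14 remained, since 4 microRNA features were not tested there, while Ppp1r14a and Oas2 did not pass. The correlation of docetaxel effects between genotypes rose from 0.633 to 0.710 with at least 1 CPM in 3 libraries and 0.714 with protein-coding genes only, where genes with few counts are fewer, and ranged from 0.574 to 0.649 without 1 library. That of genotype differences rose from 0.568 to 0.705 and 0.678, was 0.649 in the 6-library fits, and ranged from 0.514 to 0.566 without 1 library, the lowest without wild-type DMSO library 1.

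Whether the replicate numbers pair the libraries was not settled. Of 18 same-numbered pairs, 4 had deviations correlated above 0.1 (−0.272 to 0.346), and 6 of 12 libraries correlated best with their own number. With the replicate block the interaction gave 48 genes, 16 of the 17 among them, and 33 at least 2-fold. The same fit gave 4510 and 2700 genes for docetaxel in wild-type and knockout-labelled cells, against 4406 and 2499 without the block. For the genotypes under DMSO and after docetaxel it gave 2534 and 943, against 2454 and 915. The block added 3 list calls, the collagens with docetaxel in knockout-labelled cells (adjusted p = 0.0487), NF-κB targets between genotypes under DMSO (0.0364) and the mesenchymal program between genotypes after docetaxel (0.0355), and 7 of the named genes lost their call. Losses of named-gene calls numbered 100 without the 2 libraries richest in Gm23935 and 35 with only the 6 libraries compared. They numbered 13 each with GC correction, which also added 1 call, and limma-voom, and 12 with upper-quartile scaling. An estimated correlation removed 47 list calls. With fry 16 were lost and 24 gained, and of the lists that passed camera 14 of 17, 14 of 16, 5 of 7, 3 of 4 and 0 of 8 passed fry for docetaxel in wild-type and in knockout-labelled cells, the genotypes under DMSO and after docetaxel, and the interaction. In its mixed form fry passed 11 lists for the interaction. With GC-corrected values 5 list calls were gained and 4 lost, mitosis (adjusted p = 0.0865) and mitochondrially encoded genes (0.0619) with docetaxel in knockout-labelled cells, and ligands and matrix (0.0658) and NF-κB targets (0.0571) for the interaction. Over the omissions of 1 library, the 476 calls of named genes were lost in 473 of 2922 refits and kept in 2449. At these depths and library numbers, interaction changes of log2 0.5 were recovered for 8.96% of simulated genes, with a median SE of 0.206 for the interaction and 0.145 to 0.147 for the pairwise comparisons.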

Other observations

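The tests in this part were chosen after results were seen, apart from the gene lists. Stemness and breast tumour-initiating markers did not pass as a list with docetaxel (camera adjusted p = 0.552 in wild-type and 0.743 in knockout-labelled cells). Of 17 genes, 5 rose and 3 fell in wild-type cells and 4 rose and 2 fell in knockout-labelled cells (5 and 3, and 4 and 5, adjusted over the list alone). The surface antigen gene Ly6a rose from 17.2 ± 4.76 to 86.5 ± 26.3 CPM in wild-type and from 10.3 ± 1.60 to 76.8 ± 16.5 CPM in knockout-labelled cells, and Notch3 fell from 35.3 ± 4.99 to 11.3 ± 1.31 CPM and from 59.0 ± 5.32 to 22.3 ± 0.624 CPM. Among drug efflux and taxane metabolism genes, 6 of 13 rose and 3 fell in wild-type cells (8 and 4 adjusted over the list alone; camera adjusted p = 0.221), with the efflux pump gene Abcb1b going from 18.8 ± 1.38 to 26.2 ± 0.879 CPM. In knockout-labelled cells 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.261), with Abcg2 going from 5.21 ± 0.521 to 10.7 ± 2.10 CPM. The mesenchymal program did not pass either (camera adjusted p = 0.938 and 0.585), with 3 of 14 genes risen and 4 fallen in wild-type and 1 and 4 in knockout-labelled cells (4 and 4, and 1 and 4, adjusted over the list alone). Vim fell with docetaxel in both genotypes, from 543 ± 109 to 314 ± 28.9 CPM and from 367 ± 6.66 to 218 ± 19.8 CPM, while Zeb2 rose from 17.3 ± 2.07 to 25.9 ± 3.33 CPM and from 10.8 ± 0.586 to 16.6 ± 1.78 CPM.

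On some chromosomes the median over the tested protein-coding genes was lower in the knockout-labelled cells. The median log2 differences under DMSO and after docetaxel were −0.27 and −0.21 on chromosome 3 (598 genes), −0.16 and −0.18 on chromosome 8 (687 genes), −0.26 and −0.22 on chromosome 14 (424 genes) and −0.27 and −0.20 on chromosome 18 (311 genes). After GC correction they were −0.25 and −0.22, −0.16 and −0.18, −0.24 and −0.23, and −0.23 and −0.22. Chromosome 13 had −0.10 and −0.04, and the highest median on any chromosome under DMSO was 0.08. These are values with no test.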
